A study of Drosophila melanogaster with 8 samples.

How the data were processed

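Poly(A)+ RNA was sequenced from dissociated Drosophila melanogaster testes. In each of 2 strains a GAL4 driver switched on green fluorescent protein in part of the somatic cyst cells, the support cells that enclose the germline. Per the labels, tj-GAL4 marked early cyst cells and eya-GAL4 marked mature ones. Fluorescent cells were collected by sorting, and the unsorted suspension of each strain served as its control. This gave 4 groups of 2 libraries, 8 libraries in all, which the labels call biological replicates. The tj-GAL4 replicate 1 libraries carry 6-base indexes and the other 6 libraries carry 8-base indexes. The value table numbers the eya-GAL4 unsorted libraries 3 and 4 where the sample titles number them otherwise, so they are called replicates 3 and 4 here and were paired with no sorted library.

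The authors list FastQC, Bowtie 1.2.2, HTSeq and DESeq2 and the genome build dm6. The annotation release, the strand setting, the handling of reads with several matches and the other tool versions are not given in the sources used here. Reads of overlapping antisense genes and of close paralogs can therefore not be assigned with certainty. The deposited table holds raw counts of reads per gene for 16018 genes, one column per library, which per the file headers come from HTSeq. It also holds RPM (reads scaled by a library total) as computed by the authors and the gene length in nucleotides as deposited. Dividing counts by RPM gave 1 total per library, from 30669063 to 38507084, and the gene counts made up 28.0% to 71.6% of it. What else this total counts is not given in the sources used here. A further 20 columns, holding ratios, means and length-scaled values (RPKM) of the authors, were not used. Of the gene names, 15164 matched a current symbol of the reference annotation, 798 matched a synonym and 56 matched nothing. A dm6 position was found for 15960 genes.

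Total gene counts per library ran from 10771009 to 25344721. Intervals on counts cover counting error only, because reads without molecular identifiers are not independent molecules. Shares of a single library are given with Wilson 95% intervals, and ratios that involve 1 to 3 reads with exact (Clopper-Pearson) 95% intervals. Where a group had 0 reads, the fold is a lower bound against 3 reads over the group.

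The comparisons, gene lists, naming rule, threshold and most alternatives were chosen before the data were examined. That plan named limma on log2(RPM + 1), because only RPM was foreseen. As the table turned out to hold raw counts, the test became edgeR 4.0.16 (quasi-likelihood, TMM scaling) on the counts, and the planned limma test was kept as an alternative. Genes with a CPM (counts scaled by the summed gene counts and the TMM factor) of at least 1 in at least 2 libraries were tested, 12570 genes. All 4 groups were fitted together with 4 residual degrees of freedom, because a group of 2 leaves only 1 degree of freedom for its own spread. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05, two-sided. Fold changes are log2 with a standard error (SE) taken as the absolute log2 fold change over the root of the quasi-likelihood F. CPM values are means with SD over the 2 libraries of a group. There were 5 comparisons: sorted against unsorted cells for each driver, tj-GAL4 against eya-GAL4 sorted cells, tj-GAL4 against eya-GAL4 unsorted cells, and the difference of the 2 enrichments as an interaction. The 2 enrichments share no library, but all comparisons share each gene's estimate of spread, so leaving out a library of one strain also moves the calls of the other. The replicates were not equally spread, as 4741 genes differed by more than 2-fold in tj-GAL4 unsorted and 759 in eya-GAL4 sorted cells. Counts of calls depended on this sharing. Fitted on the compared groups alone, the tj-GAL4 enrichment gave 257 calls against 1428, and the sorted comparison 1275 against 14.

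The naming rule took tj and eya, after which the drivers are named, then the 12 largest rises and the 12 largest falls among called genes with a mean RPM of at least 5, no overlap between the groups compared and a symbol that is not a CG or CR number, for the 2 enrichments and the sorted comparison. For the other 2 comparisons it took the 5 largest each way. It also took the 4 members of each list with the smallest p. A total of 30 lists were fixed: markers of early cyst cells, mature cyst cells, hub, early germline, spermatocytes, spermatids, muscle, accessory gland, pigment cells and terminal epithelium, hemocytes, fat body and neurons; JAK-STAT, EGFR, Hedgehog, ecdysone, insulin and TOR, and BMP and TGF-beta signalling; septate junctions, adherens and gap junctions, integrins and basement membrane, endocytosis and lysosome, V-ATPase, DNA replication, the somatic piRNA pathway, heat shock, immediate early genes, ribosomal proteins, oxidative phosphorylation and proteasome. A list of gut enzymes was added after the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Each was also tested with an estimated correlation, and with fry, which tests whether the genes of a list move on balance one way.

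The alternatives were median-of-ratios scaling, no filter, a filter at 5 CPM, a robust spread, fits on the compared groups alone, limma on log2(RPM + 1), log2(RPM + 0.1) and log2(RPM + 5), limma after quantile normalization, DESeq2 1.42.0, a replicate block over the tj-GAL4 libraries, a minimum log2 change of 1, leaving out each library in turn, and leaving out both libraries with 6-base indexes. Chosen after the data were examined were the fits without mitochondrially encoded genes, with limma voom and sample quality weights, with library totals and no TMM, with the tj-GAL4 replicate numbers crossed, and the list tests without tj-GAL4 unsorted replicate 2. A replicate block over all 8 libraries, and one for the eya-GAL4 pairs, could not be fitted because the table gives no replicate number that links the eya-GAL4 unsorted libraries to the sorted ones. A group left with 1 library was assumed to vary like the others.

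The fits were tested on simulated data with 200 genes, and a further list of 30, changed in one group at a time. Genes were independent there, each gene had the same spread in all libraries, and no library stood apart. The recovered shares and false calls therefore need not hold for comparisons with the tj-GAL4 unsorted libraries. There edgeR recovered 79.4%, 77.1%, 72.9%, 80.9% and 16.9% of genes changed 8-fold in the tj-GAL4 enrichment, the eya-GAL4 enrichment, the sorted comparison, the unsorted comparison and the interaction. For genes changed 4-fold the shares were 31.7%, 34.9%, 29.5%, 37.9% and 1.6%. DESeq2 made 28 to 46 false calls per simulated comparison, against 1 to 8 for edgeR. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.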

Results

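RNA was sequenced from sorted and unsorted cells of fly testes to describe the transcripts of early and mature somatic cyst cells. The groups were tj-GAL4 unsorted, tj-GAL4 sorted, eya-GAL4 unsorted and eya-GAL4 sorted cells, with 2 libraries each. Gene counts were 23044927 and 16696333 in tj-GAL4 unsorted replicates 1 and 2, and 14298570 and 25344721 in tj-GAL4 sorted replicates 1 and 2. They were 12280755 and 18451373 in eya-GAL4 unsorted replicates 3 and 4, and 10771009 and 20050706 in eya-GAL4 sorted replicates 1 and 2. All positions are in dm6. Unless stated otherwise, values are log2 fold changes ± SE (n = 2 libraries per group), adjusted p-values of genes come from edgeR, and those of lists come from camera.

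Sorted and unsorted cells separated along the main axis of variation. Principal component 1 held 62.9% of the variance and component 2 held 19.0%. One unsorted library, tj-GAL4 replicate 2, stood apart from all others at -114.18 on component 2, where the other 7 lay between 5.45 and 39.58. Its log2 CPM correlated at most at 0.875 with another unsorted library, across genes that are not independent replicates, whereas the other 3 unsorted libraries correlated at 0.962 or more with each other. Mitochondrially encoded genes took 31.7% of its counts (Wilson 95% interval 31.65% to 31.69%), against 11% in tj-GAL4 unsorted replicate 1 (10.96% to 10.98%) and 7.21% and 4.68% in eya-GAL4 unsorted replicates 3 and 4 (7.20% to 7.22% and 4.67% to 4.69%). The share was 19.6% and 11% in tj-GAL4 sorted replicates 1 and 2 (19.53% to 19.57% and 11% to 11.02%), and 15.1% and 19.8% in eya-GAL4 sorted replicates 1 and 2 (15.07% to 15.11% and 19.77% to 19.81%). Between the replicates of a group, 4741 genes differed by more than 2-fold in tj-GAL4 unsorted cells, 1311 in tj-GAL4 sorted, 814 in eya-GAL4 unsorted and 759 in eya-GAL4 sorted cells.

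**Figure D1:**
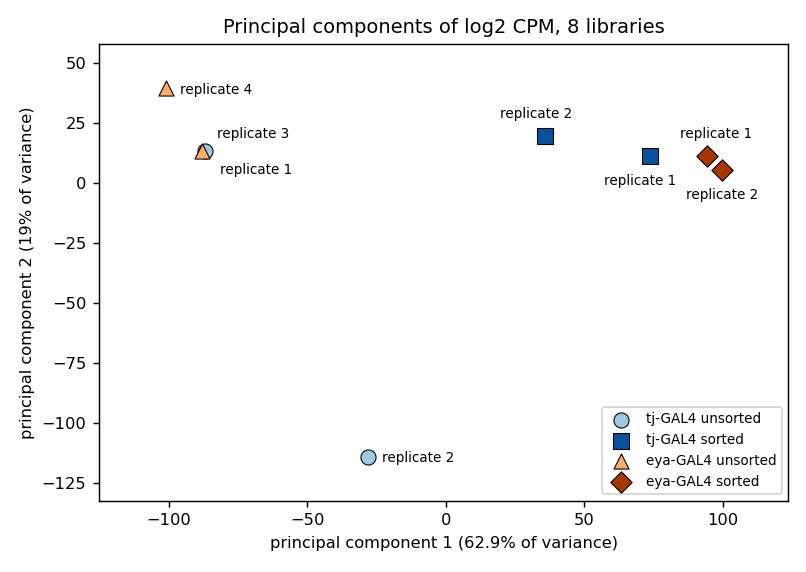
The 8 libraries on principal components 1 (62.9% of the variance) and 2 (19.0%) of log2 CPM over 12570 genes; each point is a library, coloured by group. The sorted libraries lie together on the right, and tj-GAL4 unsorted replicate 2 lies apart at -114.18 on component 2.

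The tj-GAL4 enrichment asked which transcripts mark early cyst cells. The transcription factor gene tj itself (FBgn0000964, 2L, 19464267 to 19467758) rose by 4.42 ± 0.44 (adjusted p = 0.0014), from 1.74 ± 0.310 to 37.2 ± 11.7 CPM (SD). The gene for the eyes absent transcription cofactor, eya (FBgn0000320, 2L, 6527447 to 6546976), rose by 2.63 ± 0.46 (adjusted p = 0.011), from 28.9 ± 17.2 to 179 ± 45.9 CPM. Its partner Six4 (3L, 20788886 to 20792777) rose by 3.71 ± 0.36, and the Cdc25 phosphatase gene stg, which drives entry into mitosis, rose by 3.20 ± 0.37. Mp20, which encodes a calponin-like muscle protein (2R, 13246670 to 13248880), fell by 4.39 ± 0.53 (adjusted p = 0.0028). The rise of eya was lost without tj-GAL4 sorted replicate 1 (adjusted p = 0.11), while those of tj, Six4 and stg and the fall of Mp20 held without each library in turn.

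**Figure D2:**
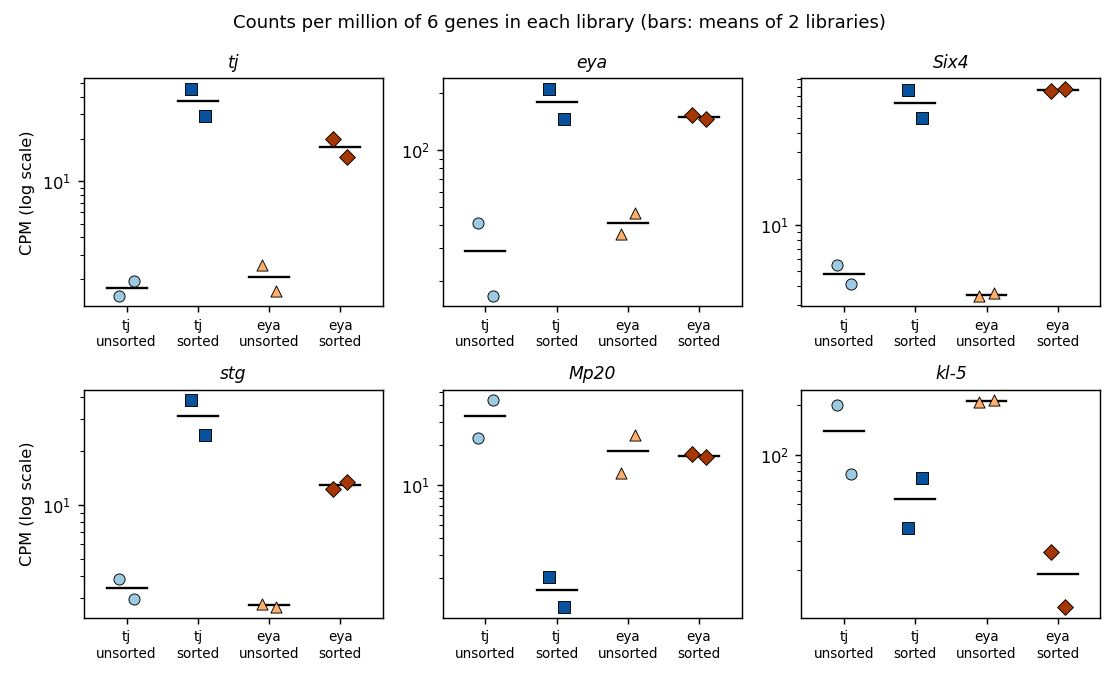
CPM (log scale) of tj, eya, Six4, stg, Mp20 and kl-5 in each library, with horizontal bars for the mean of the 2 libraries of each group. In both strains the sorted libraries lie above the unsorted ones for tj, eya, Six4 and stg, and the eya-GAL4 sorted libraries lie below the unsorted ones for kl-5.

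The largest rises in tj-GAL4 sorted cells included abundant transcripts. GstS1, a glutathione S-transferase (2R, 17093246 to 17099501), rose from 851 ± 223 to 20540 ± 5755 CPM (SD), a log2 change of 4.59 ± 0.51. The odorant binding protein gene Obp99a (3R, 29671657 to 29672334) rose from 208 ± 38.3 to 6017 ± 1967 CPM, or 4.86 ± 0.50. The cuticular protein gene Cpr66Cb had the largest rise at 6.35 ± 0.79. The forkhead genes bin and croc, the tubulin gene alphaTub85E and the serpin gene Spn43Aa rose by 5.04 ± 0.64, 4.43 ± 0.34, 4.50 ± 0.49 and 4.30 ± 0.34. With rdo, CCKLR-17D3, Kal1, Cpr97Eb and tj, these 12 genes spanned 4.28 to 6.35, and all 12 held without each library in turn.

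The 12 largest falls spanned 4.24 to 7.52 in size, and of these genes only Mp20 held without each library in turn. The ebony gene e, tnc, and the odorant binding protein genes Obp99c and Obp99b fell by 4.64 ± 0.64, 4.92 ± 0.76, 5.38 ± 1.07 and 4.70 ± 0.85. The call of e was lost without tj-GAL4 sorted replicate 1 (adjusted p = 0.08), that of tnc without sorted replicate 2 (adjusted p = 0.053), and those of Obp99c (adjusted p = 0.21 and 0.094) and Obp99b (adjusted p = 0.16 and 0.085) without either. Peritrophin-15a, of the peritrophic matrix that lines the gut, the antimicrobial peptide gene CecA1, the larval serum protein gene Lsp1beta, and Pgcl, Tsp42Ec, IM3 and lectin-37Db made up the rest. Without tj-GAL4 unsorted replicate 2, the log2 change of Peritrophin-15a went from -7.52 to -1.93 (adjusted p = 0.11), and Pgcl (adjusted p = 0.063), Tsp42Ec (0.061), IM3 (0.086) and lectin-37Db (0.066) lost their call as well. CecA1 and Lsp1beta kept it there at -1.27 and -2.84. All 7 lost their call without either tj-GAL4 sorted library (adjusted p = 0.29 to 0.33 without replicate 1 and 0.14 to 0.16 without replicate 2), and without either eya-GAL4 sorted library (adjusted p = 0.084 to 0.10). IM3 (adjusted p = 0.055 and 0.057) and CecA1 (adjusted p = 0.051 and 0.052) lost it without eya-GAL4 unsorted replicates 3 and 4 as well.

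Several cyst-cell markers rose in tj-GAL4 sorted cells. Of 12 early cyst markers tested, 7 rose and none fell (8 and 0 adjusted over the list alone), with a median of 1.90 and a list adjusted p = 1.5e-06, against adjusted p = 0.57 with an estimated correlation. They included the JAK-STAT receptor gene dome at 2.12 ± 0.32 and the piRNA gene fs(1)Yb at 2.71 ± 0.47, whose call was lost without sorted replicate 1 (adjusted p = 0.10). Of 8 mature cyst markers, 3 rose and 1 fell, the same adjusted over the list alone (median 0.67, adjusted p = 0.03, or adjusted p = 0.57 with an estimated correlation). The Six-family gene so rose by 1.92 ± 0.33, and Abd-B, a Hox gene, fell by 2.57 ± 0.58. The call of so was lost without sorted replicate 1 (adjusted p = 0.08), and that of Abd-B without each of the 4 sorted libraries (adjusted p = 0.066 to 0.21). Of 7 hub markers, 2 rose, the ligand gene hh and the N-cadherin gene CadN (3 rose and 1 fell adjusted over the list alone; median -0.48 against a mean of 0.13, adjusted p = 0.52). The call of CadN was lost without tj-GAL4 sorted replicates 1 and 2 (adjusted p = 0.16 and 0.051). In the order tj-GAL4 sorted replicates 1 and 2, either eya-GAL4 sorted library, either eya-GAL4 unsorted library, and tj-GAL4 unsorted replicates 1 and 2, leaving out a library gave 3, 5, 5, 5, 10 and 8 early cyst rises. The mature cyst rises were 1, 3, 3, 3, 3 and 5, and the hub rises 1, 1, 2, 2, 2 and 3. Without tj-GAL4 unsorted replicates 1 and 2, 2 and 1 hub genes fell. With each library left out in turn, the medians ran from 1.59 to 2.14 for early cyst, 0.56 to 1.38 for mature cyst and -0.49 to 0.98 for hub genes, the highest hub value, with the sign turned, being that without tj-GAL4 unsorted replicate 2.

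Transcripts of other testis cells and of the accessory gland were mostly lower or not called. Of 20 muscle genes 16 fell (17 adjusted over the list alone), with a median of -3.36 and a list adjusted p = 3.9e-21, or adjusted p = 0.57 with an estimated correlation. The myosin light chain gene Mlc1, the titin-like gene bt and the actin gene Act57B fell by 3.92 ± 0.48, 3.94 ± 0.50 and 3.69 ± 0.48. Of the 20, 11 to 18 fell with each library left out in turn. Of 19 early germline genes 1 rose, tud (0 adjusted over the list alone; median 0.60, adjusted p = 0.23). None of 24 spermatocyte genes was called by edgeR, over all genes or adjusted over the list alone, but their median was -1.0 (adjusted p = 9.3e-05, or adjusted p = 0.61 with an estimated correlation). Of 31 spermatid genes 2 fell, p-cup and wa-cup (5 adjusted over the list alone; median -0.94, adjusted p = 2.2e-07, or adjusted p = 0.57 with an estimated correlation). Of 19 accessory gland genes 2 fell, Acp62F and Acp76A (2 adjusted over the list alone; median -1.28, adjusted p = 0.00011, or adjusted p = 0.57 with an estimated correlation). The calls of tud, p-cup, wa-cup, Acp62F and Acp76A were each lost without 4 or more of the other libraries, tj-GAL4 sorted replicate 1 among them (adjusted p = 0.28, 0.21, 0.21, 0.17 and 0.20). In the order of libraries given for the cyst lists, leaving out a library gave 0, 1, 0, 0, 6 and 4 early germline rises (with 4 falls in the last case). The falls were 0, 0, 0, 0, 0 and 18 in the spermatocyte list, 0, 4, 0, 0, 21 and 9 in the spermatid list, and 0, 0, 0, 1, 15 and 3 in the accessory gland list. Leaving out tj-GAL4 unsorted replicate 1 also gave 1 spermatocyte rise. Over the libraries left out, medians ran from -3.91 to -2.92 for muscle, 0.04 to 0.86 for early germline, -1.50 to -0.38 for spermatocyte, -1.39 to -0.66 for spermatid and -1.84 to -0.33 for accessory gland genes. The early germline median was lowest without tj-GAL4 unsorted replicate 2, and the spermatocyte median was nearest 0 without replicate 1. The list call of the accessory gland genes was lost without tj-GAL4 unsorted replicate 2 (median -0.33, adjusted p = 0.063), while those of the muscle, spermatocyte and spermatid lists held there (medians -2.94, -1.50 and -0.75). In tj-GAL4 unsorted replicate 2 the spermatocyte and early germline lists lay at median log2 ratios of -1.16 and -0.97 to the other unsorted libraries.

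In 12 fat body genes 7 falls and 1 rise were called (7 and 2 adjusted over the list alone), with a median of -3.01 (adjusted p = 0.0021, or adjusted p = 0.57 with an estimated correlation). Fbp1 and Lsp2, which encode a receptor and a storage protein, fell by 4.72 ± 0.67 and 3.92 ± 0.75, and the iron carrier gene Tsf1 rose by 3.19 ± 0.63. The calls of Fbp1 (adjusted p = 0.08 and 0.054) and Lsp2 (adjusted p = 0.17 and 0.071) were lost without tj-GAL4 sorted replicates 1 and 2, and that of Tsf1 without replicate 1 (adjusted p = 0.13). The list call of the fat body genes was lost without tj-GAL4 unsorted replicate 2 (median -1.41, adjusted p = 0.063), and the hemocyte list passed there (median -2.23, adjusted p = 0.0016). In tj-GAL4 unsorted replicate 2 the fat body list lay at a median log2 ratio of 2.42 to the other unsorted libraries. Of 11 hemocyte genes 1 rose and 2 fell (2 and 5 adjusted over the list alone; median -1.56, adjusted p = 0.16). Of 9 pigment-cell and terminal-epithelium genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; median 0.69, adjusted p = 0.33). Of 8 neuronal genes only nSyb, a synaptic vesicle protein gene, rose, by 3.96 ± 0.50 (1 adjusted over the list alone; median 0.47, adjusted p = 0.25). In the same order, leaving out a library gave 0, 0, 3, 7, 6 and 6 fat body falls and 0, 1, 1, 1, 1 and 2 fat body rises. The pigment or terminal-epithelium rises were 0, 3, 3, 3, 3 and 3, and the neuronal rises 1, 1, 1, 1, 1 and 3. Hemocyte falls were 6 without tj-GAL4 unsorted replicate 2, 1 without eya-GAL4 unsorted replicate 4, and 0 without each other library. Hemocyte rises were 1 and 2 without tj-GAL4 unsorted replicates 1 and 2 and 0 without each other library. Pigment or terminal-epithelium falls were 3 without tj-GAL4 unsorted replicate 1 and 0 without either tj-GAL4 sorted library. The medians with a library left out ran from -3.42 to -1.41 for fat body, -2.23 to 0.39 for hemocyte, 0.19 to 1.11 for pigment and terminal-epithelium and 0.08 to 0.75 for neuronal genes. The hemocyte median turned positive without tj-GAL4 unsorted replicate 1.

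Signalling genes that rose in tj-GAL4 sorted cells were most numerous in the BMP and TGF-beta list, where 9 of 20 rose (11 adjusted over the list alone; median 1.16, adjusted p = 3.1e-06, or adjusted p = 0.57 with an estimated correlation). The ligand gene dpp rose by 3.47 ± 0.36, and the extracellular regulators magu and cv-2 and the receptor gene wit by 3.11 ± 0.40, 3.19 ± 0.42 and 2.16 ± 0.32. Of 19 EGFR genes 4 rose (9 adjusted over the list alone; median 1.0, adjusted p = 0.00021, or adjusted p = 0.57 with an estimated correlation), led by the inhibitor gene aos at 2.79 ± 0.35. Of 14 Hedgehog genes 4 rose (8 adjusted over the list alone; median 1.01, adjusted p = 0.0022, or adjusted p = 0.57 with an estimated correlation), with the ligand gene hh at 2.29 ± 0.34. Of 23 ecdysone genes 4 rose (9 adjusted over the list alone; median 1.08, adjusted p = 0.0013, or adjusted p = 0.57 with an estimated correlation). Of 14 JAK-STAT genes 3 rose (3 adjusted over the list alone; median -0.05, adjusted p = 0.50, with a sign that changed with the scaling). Of 22 insulin and TOR genes 1 rose, Ilp6, an insulin-like peptide gene, by 3.34 ± 0.34 (1 adjusted over the list alone; median 0.39, adjusted p = 0.07, or median 0.63 and adjusted p = 0.019 without tj-GAL4 unsorted replicate 2). In the same order, leaving out a library gave 4, 6, 5, 7, 9 and 15 BMP and TGF-beta rises. The EGFR rises were 1, 2, 2, 2, 6 and 13, the Hedgehog rises 1, 2, 3, 2, 7 and 8, and the ecdysone rises 0, 1, 2, 3, 7 and 14. The JAK-STAT rises were 1, 1, 1, 1, 5 and 3, and the insulin and TOR rises 1, 1, 1, 1, 3 and 8. Falls without tj-GAL4 unsorted replicate 1 were 1 EGFR, 2 JAK-STAT and 2 insulin and TOR genes. Medians ran from 0.76 to 2.0 for BMP and TGF-beta, 0.66 to 1.31 for EGFR, 0.76 to 1.3 for Hedgehog, 0.78 to 1.80 for ecdysone, -0.06 to 0.55 for JAK-STAT and 0.24 to 0.63 for insulin and TOR genes over the libraries left out.

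Some junction, lysosome and replication genes also rose. Of 24 septate junction genes 6 rose (12 adjusted over the list alone; median 1.22, adjusted p = 3.8e-05, or adjusted p = 0.60 with an estimated correlation). Of 14 adherens and gap junction genes 5 rose, led by the E-cadherin gene shg at 2.13 ± 0.39 (6 adjusted over the list alone; median 0.86, adjusted p = 0.0011, or adjusted p = 0.57 with an estimated correlation). Of 28 endocytosis and lysosome genes 8 rose, among them the glucocerebrosidase gene Gba1b at 4.13 ± 0.35 and the engulfment receptor gene drpr at 2.55 ± 0.37 (10 adjusted over the list alone; median 0.93, adjusted p = 3.1e-06, or adjusted p = 0.57 with an estimated correlation). Of 28 DNA replication genes 8 rose (11 adjusted over the list alone; median 1.08, adjusted p = 0.00043, or adjusted p = 0.57 with an estimated correlation), with the ribonucleotide reductase gene RnrS at 2.24 ± 0.29. Of 17 somatic piRNA genes 5 rose (6 adjusted over the list alone; median 0.80, adjusted p = 0.0015, or adjusted p = 0.57 with an estimated correlation), with piwi at 3.07 ± 0.35. The call of shg was lost without sorted replicate 1 (adjusted p = 0.10). In the same order, leaving out a library gave 0, 1, 1, 2, 9 and 21 septate junction rises. The adherens and gap junction rises were 0, 2, 2, 3, 6 and 13, and the endocytosis and lysosome rises 2, 6, 5, 5, 9 and 21. The DNA replication rises were 2, 3, 4, 6, 16 and 10, with 5 falls in the last case, and the somatic piRNA rises 2, 3, 4, 4, 10 and 5. Their medians ran from 0.77 to 2.07 for septate junction, 0.59 to 1.71 for adherens and gap junction, 0.63 to 1.66 for endocytosis and lysosome, 0.74 to 1.21 for DNA replication and 0.54 to 1.28 for somatic piRNA genes. Left without tj-GAL4 unsorted replicate 2, the DNA replication (median 0.74, adjusted p = 0.22) and somatic piRNA lists (median 0.54, adjusted p = 0.19) lost their list calls. The septate junction list lay at a median log2 ratio of 1.70 in tj-GAL4 unsorted replicate 2 to the other unsorted libraries.

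The remaining lists gave few calls in tj-GAL4 sorted cells. Of 23 integrin and basement membrane genes 2 rose and 2 fell (3 and 3 adjusted over the list alone; median 0.64, adjusted p = 0.46). The collagen IV genes vkg and Col4a1 fell by 3.07 ± 0.66 and 2.97 ± 0.71. Both calls were lost without each of the 4 sorted libraries (adjusted p = 0.063 to 0.24). Of 16 heat shock genes 3 rose (3 adjusted over the list alone; median 0.23, adjusted p = 0.33). Of 15 immediate early genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; median -0.09, adjusted p = 0.91, with a sign that changed with the scaling). Of 31 proteasome genes 4 rose (6 adjusted over the list alone; median 0.28, adjusted p = 0.042, or adjusted p = 0.68 with an estimated correlation). For 18 V-ATPase genes (median -0.50, adjusted p = 0.33), 88 ribosomal protein genes (median 0.95, adjusted p = 3.3e-05, or adjusted p = 0.68 with an estimated correlation) and 89 oxidative phosphorylation genes (median 0.19, adjusted p = 0.62), edgeR called 0 genes, over all genes or adjusted over the list alone. In the same order, leaving out a library gave 0, 1, 2, 1, 4 and 11 integrin and basement membrane rises and 0, 0, 0, 2, 6 and 4 falls. The heat shock rises were 1, 1, 1, 1, 3 and 5, the proteasome rises 0, 1, 1, 1, 5 and 7, and the immediate early rises 0, 1, 1, 1, 1 and 7. Further, 3 heat shock and 5 immediate early genes fell without tj-GAL4 unsorted replicate 1. Without tj-GAL4 unsorted replicate 2, 11 V-ATPase genes rose and 1 fell, 81 ribosomal protein genes rose, and 33 oxidative phosphorylation genes rose and 4 fell. Without tj-GAL4 unsorted replicate 1, 10, 1 and 2 genes of these lists fell. As a list, proteasome genes did not pass without tj-GAL4 unsorted replicate 2 (median 0.19, adjusted p = 0.16), whereas V-ATPase (1.22, adjusted p = 0.014), oxidative phosphorylation (0.74, adjusted p = 0.0026) and immediate early genes (1.18, adjusted p = 0.037) passed. Over the libraries left out, the medians went from 0.30 to 2.05 for ribosomal protein, -1.09 to 1.22 for V-ATPase, -0.08 to 0.74 for oxidative phosphorylation and 0.19 to 0.36 for proteasome genes, and from 0.16 to 0.96 for integrin and basement membrane, -0.06 to 0.69 for heat shock and -0.68 to 1.18 for immediate early genes. The ribosomal protein median was lowest without tj-GAL4 unsorted replicate 1 and highest without replicate 2. In unsorted replicate 2 the V-ATPase and ribosomal protein lists lay at median log2 ratios of 2.77 and 1.76 to the other unsorted libraries.

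In all, 1129 genes rose and 299 fell in tj-GAL4 sorted cells out of 12570 tested, and 3825 had an unadjusted p under 0.05. Without tj-GAL4 unsorted replicate 2, 3113 rose and 1350 fell, and 1378 of the 1428 calls were kept. Without unsorted replicate 1, 1675 rose and 1670 fell. Rises and falls were 257 and 20 without sorted replicate 1, and 620 and 55 without sorted replicate 2. They were 722 and 186, and 724 and 188, without eya-GAL4 unsorted replicates 3 and 4, and 599 and 90, and 594 and 89, without eya-GAL4 sorted replicates 1 and 2. The share of rises among the calls, 79.1% with all libraries, thus ran from 50.1% to 92.8%. Of 100 named genes called, 32 were called without each library in turn.

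The eya-GAL4 enrichment asked the same of mature cyst cells. Six4 rose by 4.46 ± 0.37 (adjusted p = 0.00031), from 3.49 ± 0.0953 to 76.8 ± 1.71 CPM (SD), and so rose by 2.41 ± 0.34. The driver's own gene eya rose by 1.86 ± 0.45 (adjusted p = 0.013), from 41.1 ± 7.36 to 149 ± 5.16 CPM. The gene tj rose too, by 3.06 ± 0.41 (adjusted p = 0.0016), from 2.10 ± 0.641 to 17.4 ± 3.56 CPM. The Y-linked genes kl-2 (Y, 573088 to 664173), kl-3 (Y, 336381 to 563165) and kl-5 (Y, 22250 to 137486), which encode sperm-tail dynein heavy chains made in spermatocytes, fell by 4.42 ± 0.65, 3.67 ± 0.67 and 3.50 ± 0.61. The call of eya was lost without each eya-GAL4 library (adjusted p = 0.085 and 0.07 without unsorted replicates 3 and 4, and 0.061 and 0.065 without sorted replicates 1 and 2), and the others named here held without each library.

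The largest rises in eya-GAL4 sorted cells included abundant transcripts. The odorant binding protein gene Obp44a (2R, 8134170 to 8135315) rose from 335 ± 27.2 to 23430 ± 3894 CPM (SD), a log2 change of 6.13 ± 0.58, and Obp99a rose from 113 ± 14.2 to 13250 ± 2858 CPM, or 6.88 ± 0.55. Transferrin, Tsf1, rose by 5.69 ± 0.71. The peroxiredoxin gene Prx2540-2 and the glutathione S-transferase gene GstD3 rose by 5.90 ± 0.44 and 5.82 ± 0.42, with the caveat that both have close paralogs, as have scpr-A and scpr-C at 5.67 ± 0.96 and 5.66 ± 1.0. Lst, which encodes the hormone limostatin, rose by 5.78 ± 0.61, and Kaz1-ORFB, Cpr66Cb and Cpr97Eb by 5.86 ± 0.60, 6.03 ± 0.76 and 5.67 ± 0.59. The gene whe had 335 reads in sorted and 1 read in unsorted cells, a ratio per read depth of 334 (exact 95% interval 59.5 to 13200), and lost its call without each eya-GAL4 library (adjusted p = 0.068 to 0.11); the other 11 held without each library.

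The largest falls after kl-2 were of Pkd2, a sperm channel gene, at -3.91 ± 0.75, the mechanosensitive channel gene Pzl at -3.89 ± 0.92, and dpy, which encodes a giant extracellular matrix protein, at -3.82 ± 0.32. The calnexin gene Cnx14D fell by 3.63 ± 0.47, and the dynein gene Dhc98D fell by 3.58 ± 0.74. The rest were the mannosidase genes LManVI and LManIII, lint and ACXE. Of the 12, kl-2, dpy, kl-3, Cnx14D and kl-5 held without each library. Without eya-GAL4 sorted replicate 2 the calls of Pkd2 (adjusted p = 0.062), Pzl (0.10), Dhc98D (0.078), LManVI (0.11), LManIII (0.10), lint (0.11) and ACXE (0.12) were lost. Pzl was also lost without unsorted replicate 4 (adjusted p = 0.052), lint and ACXE without unsorted replicate 4 (0.063 and 0.07) and sorted replicate 1 (both 0.099). LManVI and LManIII were also lost without unsorted replicate 3 (adjusted p = 0.31 and 0.27, at -1.24 and -1.27), sorted replicate 1 (0.17 and 0.16) and tj-GAL4 sorted replicates 1 (0.062 and 0.056) and 2 (0.06 and 0.054).

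Most spermatocyte genes and part of the other germline genes fell in eya-GAL4 sorted cells. Of 24 spermatocyte genes 21 fell (23 adjusted over the list alone), with a median of -2.08 (adjusted p = 1.8e-08, or adjusted p = 0.67 with an estimated correlation). The meiotic arrest gene can fell by 2.40 ± 0.44, a call lost without sorted replicate 2 (adjusted p = 0.055). Of 31 spermatid genes 13 fell (12 adjusted over the list alone; median -1.06, adjusted p = 9.4e-05, or adjusted p = 0.67 with an estimated correlation), with r-cup at -1.93 ± 0.32. Of 19 early germline genes 3 rose and 6 fell (3 and 6 adjusted over the list alone; median -0.70, adjusted p = 0.14), the piRNA gene AGO3 falling by 2.18 ± 0.39. Of 19 accessory gland genes 14 fell (14 adjusted over the list alone; median -1.68, adjusted p = 3.5e-05, or adjusted p = 0.67 with an estimated correlation), with aqrs and the seminal fluid gene Acp36DE at -2.23 ± 0.36 and -2.68 ± 0.48. Without unsorted replicates 3 and 4 and sorted replicates 1 and 2 in turn, the falls were 13, 8, 7 and 5 in the spermatocyte list, and 4, 2, 3 and 1 in the spermatid list. They were 7, 2, 4 and 2 in the accessory gland list, and 3, 2, 1 and 1, beside 0, 0, 1 and 2 rises, in the early germline list. Without either tj-GAL4 unsorted library, 22 spermatid genes fell. With each of the 8 libraries left out, medians ran from -2.23 to -1.94 for spermatocyte, -1.15 to -0.97 for spermatid, -0.88 to -0.52 for early germline and -1.83 to -1.40 for accessory gland genes.

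Cyst markers rose in part. Of 12 early cyst markers 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 1.94, adjusted p = 0.053), with dome at 2.30 ± 0.32 and stg at 2.23 ± 0.36. Of 8 mature cyst markers 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 1.67, adjusted p = 0.028, or adjusted p = 0.67 with an estimated correlation). Of 9 pigment-cell and terminal-epithelium genes 5 rose (5 adjusted over the list alone; median 1.75, adjusted p = 0.0085, or adjusted p = 0.67 with an estimated correlation), among them the xanthine dehydrogenase gene ry at 3.65 ± 0.38, the ligand gene Wnt2 at 4.77 ± 0.59 and the pigment transporter gene w, a common transgene marker, at 3.93 ± 0.53. Of 7 hub markers 2 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.11, adjusted p = 0.66, with a sign that changed with the scaling). Of 20 muscle genes 2 rose and 5 fell (2 and 4 adjusted over the list alone; median -0.69, adjusted p = 0.063). Of 11 hemocyte genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; median -0.63, adjusted p = 0.85), and of 12 fat body genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; median -0.63 against a mean of 0.47, adjusted p = 0.89). Of 8 neuronal genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; median 0.23, adjusted p = 0.94, with a sign that changed with the scaling). Without unsorted replicates 3 and 4 and sorted replicates 1 and 2 in turn, 4, 3, 5 and 5 early cyst, 2, 2, 2 and 2 mature cyst, and 1, 1, 1 and 1 hub genes rose. Likewise 0, 0, 1 and 0 muscle, 2, 1, 2 and 1 hemocyte, 2, 1, 2 and 2 fat body, and 1, 1, 2 and 2 neuronal genes rose. Falls were 1, 0, 0 and 0 in the hub list, 3, 1, 2 and 1 in the muscle list, 2, 1, 1 and 1 in the neuronal list, and 0 in the cyst, hemocyte and fat body lists. Without either tj-GAL4 unsorted library, falls were 2 early cyst, 2 hub, 9 muscle, 4 hemocyte, 3 fat body and 1 pigment or terminal-epithelium gene, and the fall in the mature cyst list was lost without either tj-GAL4 sorted library. Medians with a library left out ran from 1.71 to 2.03 for early cyst, 1.53 to 1.79 for mature cyst, 1.58 to 2.10 for pigment and terminal-epithelium and -0.20 to 0.46 for hub genes. They ran from -1.01 to -0.25 for muscle, -1.04 to -0.31 for hemocyte, -0.95 to 0.63 for fat body and -0.19 to 1.11 for neuronal genes, so that the signs of the hub, fat body and neuronal medians depended on 1 library.

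Most ribosomal protein genes rose in eya-GAL4 sorted cells. Of 88 tested, 81 rose and 2 fell (81 and 4 adjusted over the list alone), with a median of 2.84 (adjusted p = 1.4e-15, or adjusted p = 0.67 with an estimated correlation). Of 89 oxidative phosphorylation genes 61 rose and 7 fell (66 and 10 adjusted over the list alone; median 1.59, adjusted p = 4.9e-05, or adjusted p = 0.68 with an estimated correlation), the cytochrome oxidase genes COX7A and COX8 rising by 3.36 ± 0.54 and 3.37 ± 0.57. Of 18 V-ATPase genes 8 rose and 2 fell (12 and 2 adjusted over the list alone; median 2.01, adjusted p = 0.052). Of 31 proteasome genes 11 rose (10 adjusted over the list alone; median 0.52, adjusted p = 0.006, or adjusted p = 0.67 with an estimated correlation), a median that went as low as -0.16 with another scaling. Without unsorted replicates 3 and 4 and sorted replicates 1 and 2 in turn, 47, 11, 74 and 47 ribosomal protein genes rose, 11, 7, 38 and 13 oxidative phosphorylation genes, 1, 0, 2 and 1 V-ATPase genes, and 5, 6, 8 and 7 proteasome genes. Without either tj-GAL4 sorted library 5 V-ATPase genes rose, and without either tj-GAL4 unsorted library 15 did, with 5 ribosomal protein and 14 oxidative phosphorylation genes falling. The 4 medians ran from 2.61 to 3.04 for ribosomal protein, 1.38 to 1.74 for oxidative phosphorylation, 1.87 to 2.18 for V-ATPase and 0.40 to 0.70 for proteasome genes over the libraries left out.

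Many lysosome and junction genes and some hormone genes rose in eya-GAL4 sorted cells as well. Of 28 endocytosis and lysosome genes 24 rose (24 adjusted over the list alone; median 2.30, adjusted p = 2.1e-09, or adjusted p = 0.67 with an estimated correlation), led by Npc2a, a sterol carrier gene, at 5.08 ± 0.46 and Gba1b at 5.0 ± 0.37. Of 24 septate junction genes 19 rose (21 adjusted over the list alone; median 2.10, adjusted p = 5.6e-07, or adjusted p = 0.67 with an estimated correlation), with the claudin genes sinu and pck at 3.84 ± 0.55 and 3.58 ± 0.53. Of 14 adherens and gap junction genes 9 rose (10 adjusted over the list alone; median 1.83, adjusted p = 0.0085, or adjusted p = 0.67 with an estimated correlation). Of 23 integrin and basement membrane genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; median 1.32, adjusted p = 0.048, or adjusted p = 0.67 with an estimated correlation). Of 23 ecdysone genes 12 rose (12 adjusted over the list alone; median 1.38, adjusted p = 0.003, or adjusted p = 0.67 with an estimated correlation), with the steroid hydroxylase gene sad at 4.22 ± 0.52 and the ecdysone importer gene Oatp74D at 3.30 ± 0.41. Of 16 heat shock genes 6 rose (6 adjusted over the list alone; median 1.34, adjusted p = 0.0049, or adjusted p = 0.67 with an estimated correlation), with Hsp67Ba at 5.15 ± 0.40. Without unsorted replicates 3 and 4 and sorted replicates 1 and 2 in turn, the rises were 16, 10, 19 and 16 in the endocytosis and lysosome list, 12, 7, 12 and 15 in the septate junction list, and 4, 2, 4 and 7 in the adherens and gap junction list. They were 4, 4, 7 and 7 in the integrin list, 8, 7, 8 and 8 in the ecdysone list, and 4, 3, 4 and 3 in the heat shock list. Without tj-GAL4 unsorted replicates 1 and 2, 10 and 9 heat shock genes rose and 4 integrin and basement membrane genes fell. Leaving out a library gave medians of 2.17 to 2.44 for endocytosis and lysosome, 1.95 to 2.30 for septate junction, 1.52 to 1.97 for adherens and gap junction, 1.08 to 1.45 for integrin and basement membrane, 1.04 to 1.72 for ecdysone and 1.18 to 1.44 for heat shock genes.

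Of 20 BMP and TGF-beta genes 15 rose and 1 fell in eya-GAL4 sorted cells (15 and 2 adjusted over the list alone; median 2.16, adjusted p = 0.00018, or adjusted p = 0.67 with an estimated correlation), with dpp at 3.64 ± 0.37. Of 19 EGFR genes 11 rose (11 adjusted over the list alone; median 1.41, adjusted p = 0.011, or adjusted p = 0.67 with an estimated correlation). Of 14 Hedgehog genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 1.16, adjusted p = 0.13), with hh at 3.86 ± 0.36. Of 22 insulin and TOR genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.46, adjusted p = 0.14), and of 14 JAK-STAT genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; median 0.07, adjusted p = 0.94). Of 28 DNA replication genes 9 rose and 5 fell (9 and 6 adjusted over the list alone; median 0.09, adjusted p = 0.88), and of 17 somatic piRNA genes 5 rose and 3 fell (5 and 3 adjusted over the list alone; median 0.26, adjusted p = 0.64). The sign of the median changed with the scaling in these last 4 lists. Of 15 immediate early genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.79, adjusted p = 0.13). Without unsorted replicates 3 and 4 and sorted replicates 1 and 2 in turn, the rises were 8, 8, 9 and 9 in the BMP and TGF-beta list, 5, 4, 4 and 5 in the EGFR list, and 1, 1, 2 and 4 in the Hedgehog list. They were 4, 3, 4 and 4 in the insulin and TOR list, 2, 1, 2 and 2 in the JAK-STAT list, 3, 4, 4 and 4 in the DNA replication list, 2, 2, 3 and 3 in the somatic piRNA list, and 4, 2, 4 and 4 in the immediate early list. At most 1 gene of each of these lists fell there, 0 of the DNA replication list, and without either tj-GAL4 unsorted library 9 DNA replication, 4 JAK-STAT and 4 insulin and TOR genes fell. Medians over the libraries left out ran from 1.85 to 2.28 for BMP and TGF-beta, 1.24 to 1.68 for EGFR, 0.94 to 1.36 for Hedgehog and 0.20 to 0.75 for insulin and TOR genes, and from -0.13 to 0.25 for JAK-STAT, 0.03 to 0.30 for DNA replication, 0.03 to 0.58 for somatic piRNA and 0.47 to 1.19 for immediate early genes.

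**Figure D3:**
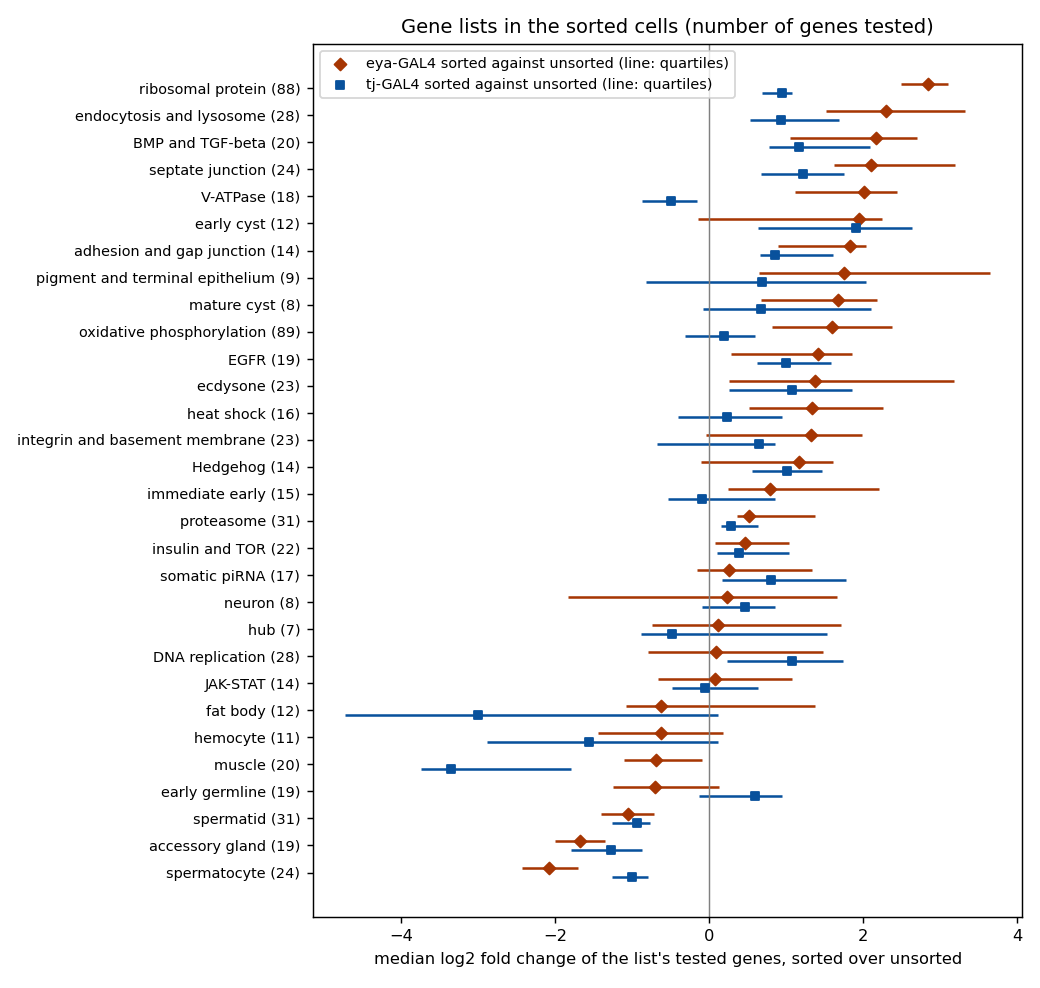
Median log2 fold change of sorted over unsorted cells for the tested genes of each of the 30 lists (number tested in brackets), squares for tj-GAL4 and diamonds for eya-GAL4, with lines from the lower to the upper quartile. Ribosomal protein genes lie at 2.84 in eya-GAL4 cells and spermatocyte genes at -2.08; medians of the hub, JAK-STAT, neuron, DNA replication, somatic piRNA, insulin and TOR, proteasome and immediate early lists changed sign with the scaling in at least one strain.

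In all, 3516 genes rose and 2512 fell in eya-GAL4 sorted cells, and 7288 had an unadjusted p under 0.05. The split between rises and falls depended on the scaling: 58.3% of calls were rises with TMM, 46.7% after quantile normalization and 37.8% with library totals. It depended on single libraries too, with 50.9% to 91.2% rises when each library was left out in turn. Rises and falls were 1648 and 568, and 1146 and 232, without unsorted replicates 3 and 4, and 2146 and 424, and 1781 and 171, without sorted replicates 1 and 2. Mitochondrially encoded genes took a larger share of the counts in eya-GAL4 sorted (15.1% and 19.8%) than in unsorted libraries (7.21% and 4.68%), and a fit without these genes called 3565 rises and 2546 falls. Of 131 named genes called, 81 were called without each library in turn.

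Most transcripts enriched by the tj-GAL4 sort were also enriched by the eya-GAL4 sort. Of the 1129 genes that rose in tj-GAL4 sorted cells, 1075 also rose in eya-GAL4 sorted cells, where 315.8 would be shared by independent lists, and 0 fell (edgeR). Of the 299 that fell, 99 also fell (59.8 for independent lists) and 4 rose. The fold changes of the 2 enrichments correlated across 12570 genes, which are not independent replicates, at Pearson r = 0.668 and Spearman rho = 0.728, at 0.848 and 0.865 without tj-GAL4 unsorted replicate 2, and at 0.418 and 0.423 without tj-GAL4 unsorted replicate 1. Without each other library r lay between 0.579 and 0.713. With tj-GAL4 unsorted replicate 1 left out, 1302 of the 1675 genes that rose in tj-GAL4 sorted cells also rose in eya-GAL4 sorted cells and 123 fell there, and of the 1670 that fell 690 also fell and 237 rose. The genes that rose in both were 2931 without tj-GAL4 unsorted replicate 2, 257 and 606 without tj-GAL4 sorted replicates 1 and 2, 633 and 567 without eya-GAL4 unsorted replicates 3 and 4, and 547 and 554 without eya-GAL4 sorted replicates 1 and 2. The genes that fell in both were 1171 and 690 without tj-GAL4 unsorted replicates 2 and 1, and between 5 and 34 without any other library.

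The comparison of tj-GAL4 with eya-GAL4 sorted cells asked what sets early apart from mature cyst cells; driver and strain differ along with the stage. The gene na, which encodes a sodium leak channel (FBgn0002917, X, 14266367 to 14277416), was 4.82 ± 0.57 higher in tj-GAL4 sorted cells (adjusted p = 0.043), at 39.6 ± 12 against 1.37 ± 0.470 CPM (SD). It was also at 53.8 ± 32.6 against 8.6 ± 1.42 CPM in the unsorted cells of the same strains. Early cyst genes with the smallest p were stg at 1.29 ± 0.34 (adjusted p = 0.27) and the JAK-STAT target gene zfh1 at 1.56 ± 0.42 (adjusted p = 0.28), which passed the test without tj-GAL4 unsorted replicate 2 (adjusted p = 0.027 and 0.01). The genes tj at 1.09 ± 0.38 (adjusted p = 0.42) and eya at 0.26 ± 0.43 (adjusted p = 0.79) did not pass it either. The call of na was lost without each of the other libraries except the tj-GAL4 unsorted ones (adjusted p = 0.31 and 0.68 without tj-GAL4 sorted replicates 1 and 2, 0.062 and 0.064 without eya-GAL4 unsorted replicates 3 and 4, and 0.52 and 0.59 without eya-GAL4 sorted replicates 1 and 2).

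Between the sorted groups, 3 genes were called higher in tj-GAL4 cells and 11 lower, with 1356 at an unadjusted p under 0.05. Fitted on these 2 groups alone, edgeR called 1275 genes. The few calls of the shared fit therefore do not show that the 2 sorts hardly differed. Apart from na, the genes called in the shared fit lie outside the naming rule and were chosen after their values were seen. CG33667 was 3.75 ± 0.50 and the RNA gene lncRNA:CR40469 7.25 ± 0.97 higher in tj-GAL4 cells. The RNA gene lncRNA:CR34335, with 646 reads in tj-GAL4 and 110616 in eya-GAL4 sorted cells, was lower by a log2 change of -7.79 ± 0.94. CG3526, CG12498, CG34205, CG15550 and the zinc transporter gene Zip42C.1 had 1, 1, 1, 2 and 3 reads in tj-GAL4 sorted cells against 1501, 394, 620, 371 and 592 in eya-GAL4 sorted cells. Their ratios per read depth were 1930, 507, 797, 239 and 254, with exact 95% intervals of 346 to 76300, 90.4 to 20100, 143 to 31500, 65.6 to 1980 and 86.4 to 1230. CR45499 had 0 reads in tj-GAL4 sorted cells and was at least 49.4-fold lower. CG13857, CG14219, CG15674 and CG16884 were at -4.28 ± 0.50, -4.71 ± 0.61, -4.60 ± 0.42 and -4.11 ± 0.48. The count of 14 went to 0 without each of the 4 sorted libraries, to 5 without either eya-GAL4 unsorted library, and to 740 and 733 without tj-GAL4 unsorted replicates 1 and 2; the planned limma test called 22 and DESeq2 211.

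None of the 30 lists had a called member between the sorted groups by edgeR over all genes. Adjusted over the list alone, 3 early cyst, 1 hub, 1 muscle and 1 adherens or gap junction gene were higher in tj-GAL4 cells, and 13 muscle genes and 1 gene each of the mature cyst, pigment and terminal-epithelium, ecdysone and immediate early lists were lower. As whole lists, muscle genes (median -1.80, adjusted p = 5.6e-17) and ribosomal protein genes (median -0.75, adjusted p = 7.2e-11) were lower in tj-GAL4 sorted cells. So were endocytosis and lysosome (-0.42, adjusted p = 4.7e-05), oxidative phosphorylation (-0.51, adjusted p = 1.4e-05), proteasome (-0.28, adjusted p = 0.001) and pigment and terminal-epithelium genes (-0.49, adjusted p = 0.024), the signs of these last 4 changing with the scaling. Early germline (1.01, adjusted p = 4.7e-05), spermatocyte (0.70, adjusted p = 0.0002), spermatid (0.42, adjusted p = 0.01), DNA replication (0.64, adjusted p = 0.00076), early cyst (0.90, adjusted p = 0.0031) and somatic piRNA genes (0.44, adjusted p = 0.043) were higher. Every one of these list calls was lost with an estimated correlation (adjusted p = 0.80 with an estimated correlation). The members with the smallest p were Mp20 at -3.40 ± 0.51 (adjusted p = 0.08) and sad at -3.42 ± 0.50 (adjusted p = 0.068). Both passed without tj-GAL4 unsorted replicate 2, which is outside this comparison and enters only the shared spread and the scaling. Against eya-GAL4 sorted cells, the median log2 ratios in tj-GAL4 sorted replicates 1 and 2 were 0.89 and 0.90 for the early germline list, 0.27 and 0.99 for the spermatocyte list, and -0.07 and 0.79 for the spermatid list.

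The interaction asked which genes were enriched to a different extent by the 2 sorts. By edgeR 0 genes passed, with 1841 at an unadjusted p under 0.05 and a smallest adjusted p of 0.12; DESeq2 called 346 and the planned limma test 42. Mp20 differed by -4.27 ± 0.68 (adjusted p = 0.19), Mlc1 by -3.61 ± 0.62 (adjusted p = 0.24) and the pigment transporter gene w by -4.35 ± 0.70 (adjusted p = 0.19), and none of them passed with all libraries. Without tj-GAL4 unsorted replicate 2 these 3 passed, but the tj-GAL4 unsorted group then held a single library, and the spread came from the other groups. As a list, muscle genes differed by a median of -2.26 (adjusted p = 1.7e-15, or adjusted p = 0.52 with an estimated correlation). Of simulated genes whose enrichment was changed 8-fold, edgeR recovered 16.9%.

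The unsorted cells of the 2 strains were compared as the background of the other comparisons. The fat body gene Fbp1 was 7.03 ± 0.77 higher in tj-GAL4 unsorted cells (adjusted p = 0.039), at 37.9 ± 32.3 against 0.28 ± 0.0441 CPM (SD). The log2 change of Fbp1 was 5.65 without tj-GAL4 unsorted replicate 2. Its call was lost without eya-GAL4 unsorted replicates 3 and 4 (adjusted p = 0.36 and 0.46) and without each of the 4 sorted libraries (adjusted p = 0.15 to 0.16). By edgeR 3 genes were higher and 6 lower, with 1481 at an unadjusted p under 0.05. Named after their values were seen, the others were CG31710 and lncRNA:CR40469 at 3.11 ± 0.36 and 8.77 ± 1.05, and CG14082 and CG9518 at -5.01 ± 0.58 and -4.47 ± 0.55. CG12498 was at 1 read against 1140 (ratio per read depth 1470, exact 95% interval 264 to 58300). CG3526, lncRNA:CR46063 and CR45499 had 0 reads in tj-GAL4 unsorted cells and were at least 244-fold, 101-fold and 78.8-fold lower. As lists, ribosomal protein (median 1.15, adjusted p = 2.7e-11) and V-ATPase genes (2.04, adjusted p = 2e-05) were higher in tj-GAL4 unsorted cells, but lay at -0.05 and 0.09 without replicate 2. Fat body genes were higher at 1.89 (adjusted p = 3.3e-08), with 1 of 12 called (7 adjusted over the list alone), and accessory gland genes lower at -0.57 (adjusted p = 1.8e-05). These 2 lists lay at 0.85 and -1.45 without tj-GAL4 unsorted replicate 2, where 7 of 19 accessory gland genes were called lower. Muscle (0.85, adjusted p = 0.0014), pigment and terminal-epithelium (0.86, adjusted p = 0.0093), septate junction (1.06, adjusted p = 0.00021), integrin and basement membrane (0.60, adjusted p = 0.0034), endocytosis and lysosome (0.58, adjusted p = 0.0014), heat shock (0.81, adjusted p = 0.00021) and oxidative phosphorylation genes (0.62, adjusted p = 3.3e-06) were also higher. Spermatocyte genes were lower (-0.45, adjusted p = 0.00021). Without tj-GAL4 unsorted replicate 2 the medians were 0.37 for muscle, 0.1 for pigment and terminal-epithelium and 0.19 for integrin and basement membrane genes. The list calls of the ribosomal protein, V-ATPase, septate junction, endocytosis and lysosome, heat shock, oxidative phosphorylation and spermatocyte genes were lost without tj-GAL4 unsorted replicate 2 (adjusted p = 0.063 to 0.91). No list passed with an estimated correlation (smallest adjusted p = 0.75 with an estimated correlation). The count of 9 went to 0 without any of the 4 sorted libraries, to 2 without either eya-GAL4 unsorted library, and to 3925 and 155 without tj-GAL4 unsorted replicates 1 and 2.

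**Figure D4:**
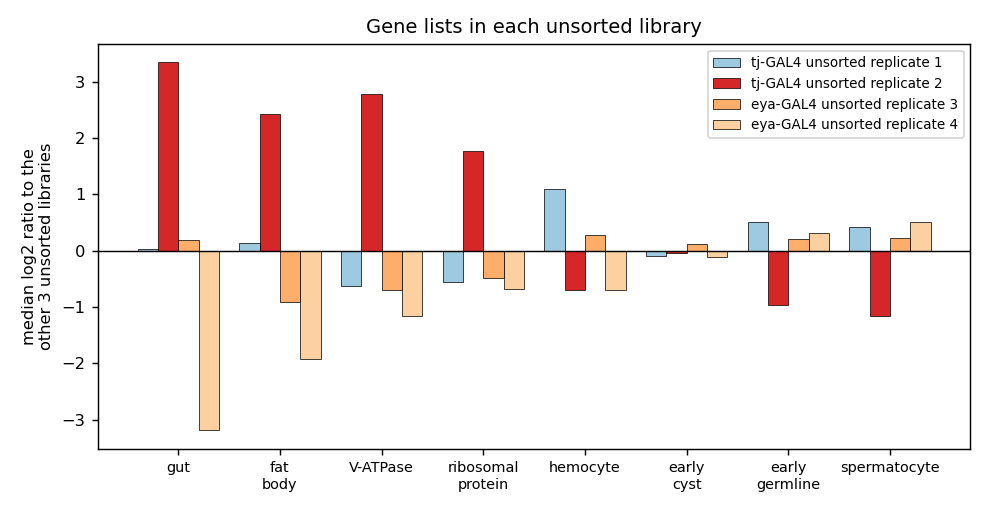
Median log2 ratio of 8 gene lists in each unsorted library to the mean of the other 3 unsorted libraries. In tj-GAL4 unsorted replicate 2 the gut, fat body, V-ATPase and ribosomal protein lists lie at 3.34, 2.42, 2.77 and 1.76, and the early germline and spermatocyte lists at -0.97 and -1.16.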

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

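Every test reported here was chosen only after the result was seen, apart from the interaction tests of the lists and the length test of the unsorted library. The enrichments of 18 gene lists differed between the tj-GAL4 and the eya-GAL4 sort by camera on the interaction. By median log2 difference, tj-GAL4 minus eya-GAL4, the muscle list differed by -2.26, V-ATPase by -2.76, fat body by -2.72, ribosomal protein by -1.92, septate junction by -1.45, pigment and terminal epithelium by -1.37, heat shock by -1.26, oxidative phosphorylation by -1.18, endocytosis and lysosome by -1.03, immediate early by -0.97, integrin and basement membrane by -0.86, and proteasome by -0.35, whose sign changed with the scaling. The early germline list differed by 1.2, spermatocyte by 1.12, DNA replication by 0.81, early cyst by 0.75, somatic piRNA by 0.68 and accessory gland by 0.40. Each of these calls was lost with an estimated correlation (adjusted p = 0.52 to 0.67 with an estimated correlation). Without tj-GAL4 unsorted replicate 2 the medians were -2.18 for muscle, -0.56 for V-ATPase, -0.97 for fat body, -0.74 for ribosomal protein, -0.28 for septate junction, -0.69 for pigment and terminal epithelium, -0.70 for heat shock and -0.68 for oxidative phosphorylation genes. They were -0.64 for endocytosis and lysosome, -0.13 for integrin and basement membrane, -0.40 for proteasome, and 0.15, with the sign turned, for immediate early genes. Early germline genes lay at 0.78 there, spermatocyte at 0.68, DNA replication at 0.48, early cyst at 0.93, somatic piRNA at 0.27 and accessory gland genes at 1.24, and the calls of the somatic piRNA and immediate early lists were lost (adjusted p = 0.16 and 0.77).

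Tj-GAL4 unsorted replicate 2 stood apart from the other unsorted libraries. A lower share of germline cells alone would raise all other cell types alike, but fat body and hemocyte lists lay 3.13 log2 units apart. This pair was chosen once its gap was seen, so its permutation p of 1e-05 decides nothing. RNA from gut or fat body may contribute, as no sort would remove it from an unsorted suspension and the gut and fat body lists lay at 3.34 and 2.42, with 27 of 30 tested gut genes and 12 of 12 fat body genes above each other unsorted library; the protease genes Jon65Aiv, Jon65Aiii and thetaTry reached 1519, 1470 and 1240 CPM. Of these lists 26 gut and 8 fat body genes had a mean of at least 1 CPM in the other unsorted libraries, and no gut gene is in another list. Loss of long transcripts stays open, since log2 ratio and gene length correlated at rho = -0.198 across 11214 genes, which are not independent replicates, against 0.078 to 0.28 in the other unsorted libraries and a bound of -0.2 set beforehand; apart from the share of germline cells, no biological explanation was tested.

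As lists, early germline, spermatocyte and spermatid genes were higher in tj-GAL4 than in eya-GAL4 sorted cells. Each of these calls was lost with an estimated correlation (adjusted p = 0.80 with an estimated correlation), and 0 of the 19, 24 and 31 members were called. Carry-over of suspension would bring muscle transcripts too, so the muscle list bounds its share at 25.7% and 14.1% in tj-GAL4 sorted replicates 1 and 2, on the scaling that left the smaller rise. After that share of the highest unsorted library was subtracted, early germline genes still lay at medians of 0.37 and 0.65 against eya-GAL4 sorted cells (permutation p = 0.42 and 0.0012, by flipping signs across genes, which are not independent replicates). Spermatocyte genes lay at -5.21 and 0.42 (permutation p = 1e-05 and 0.003) and spermatid genes at -3.06 and 0.33 (permutation p = 1e-05 and 0.00082). In replicate 1 the lower quartiles of these 2 lists were -9.87 and -11.21, with 0 and 1 genes above eya-GAL4 sorted cells. The subtracted share is an upper bound, so the negative medians of replicate 1 measure no deficit. As only replicate 2 kept a rise past the bound set, carry-over as the only cause stays open for all 3 lists. The early germline list lay at 0.89 and 0.90 against eya-GAL4 sorted cells, which argues against 1 library alone. The spermatocyte list lay at 0.27 and 0.99, the lower value lying between the bounds set, so that for it 1 library alone cannot be told apart from both. The spermatid list lay at -0.07 and 0.79, as a rise in 1 library alone would give. Earlier tests of carry-over were replaced after their values were seen. These were equal changes of the 3 lists (permutation p = 0.003), which carry-over does not predict, and spermatocyte above early germline genes (-0.15, permutation p = 0.36), which decided nothing. A comparison with a mixture of eya-GAL4 sorted cells and suspension argued against carry-over for the early germline list, and for the spermatid list once limited to the library in which it rose, but it assumed the profile of the sorted cells and was dropped. A difference between early and mature cyst cells, and the germ cells attached to them, stays open and was not tested.

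Of the 14 genes called between the sorted groups, 9 differed in the same direction by at least 1 log2 unit between the unsorted groups. A difference between the strains that is present in all cells could contribute at those 9, but need not account for their whole size. CG14219 lay at -4.71 between the sorted and -1.21 between the unsorted groups, with 9 and 20 reads in the latter. lncRNA:CR34335 lay at -7.79 and -4.07. Of the 9, 4 were called in the same direction between the unsorted groups as well: CG3526, CG12498, CR45499 and lncRNA:CR40469. These 4 lay further from 0 between the unsorted than between the sorted groups. Both suspensions hold early and mature cyst cells, so a difference between cyst cell stages as the only cause would not have separated the unsorted groups at these 4 genes. For the other 5 of the 9, not called between the unsorted groups, strain and stage cannot be told apart by this test. The remaining 5 of the 14 did not differ alike between the unsorted groups. CG13857 and CG15674 lay at 0.38 ± 0.47 and 0.58 ± 0.38 there, with 95% intervals of -0.94 to 1.69 and -0.47 to 1.64, apart from those between the sorted groups (-5.67 to -2.90 and -5.76 to -3.44). This argues against a strain difference present in all cells for these 2. CG15550, CG34205 and Zip42C.1, at 1.05 ± 1.02, 0.96 ± 0.92 and -0.24 ± 0.88, had fewer than 20 reads in at least 1 unsorted group, too few to settle it. A difference between cyst cell stages, or a strain difference in the cyst cells alone, stays open for all 5.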

How the results depend on the processing

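The fits without mitochondrially encoded genes, with voom quality weights, with library totals, with crossed tj-GAL4 numbers, and the list tests without tj-GAL4 unsorted replicate 2, were tests chosen only after the results were seen. A replicate block over all 8 libraries and one for the eya-GAL4 pairs could not be fitted. The tj-GAL4 count of 1428 stayed within 1.5 times under 9 other settings, with 1190 to 1731 calls. It was 257 on the compared groups alone, 536, 527 and 502 by limma on log2(RPM + 1), (RPM + 0.1) and (RPM + 5), 2530 by DESeq2, 399 with quality weights, 2637 with a block over crossed replicate numbers, and 3128 without both libraries with 6-base indexes. The share of rises went from 79.1% to 88.3%, 60.1%, 64.1%, 54.0%, 58.2%, 85.2%, 77.1% and 51.6% in these settings. The eya-GAL4 count of 6028 was 2188, 2598 and 1612 by the same limma tests, with 40.8%, 38.4% and 45.3% rises against 58.3%, and 9070 with quality weights. The sorted comparison, at 14, gave 46 without a filter, 1275 on the compared groups alone, 22, 32 and 22 by limma, 23 after quantile normalization, 211 by DESeq2, 155 with quality weights and 3138 without both libraries with 6-base indexes. The interaction, at 0 by edgeR with 1841 at an unadjusted p under 0.05, gave 1 without a filter, 42, 37 and 52 by limma, 346 by DESeq2, 1 with the crossed block and 5545 without both libraries with 6-base indexes. The unsorted comparison, at 9, gave 16 with median-of-ratios scaling, 48 without a filter, 0 on the compared groups alone by edgeR, 125, 113 and 156 by limma, 34 after quantile normalization, 388 by DESeq2, 5027 without both libraries with 6-base indexes and 15 with library totals.

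Leaving out each library in turn gave 277 to 4463 calls for the tj-GAL4 enrichment, 1378 to 8399 for the eya-GAL4 enrichment, 0 to 740 for the sorted comparison, 0 to 4195 for the interaction and 0 to 3925 for the unsorted comparison. Only with a library left out did the list tests of the spermatocyte and ribosomal protein genes change direction between the unsorted groups. Without tj-GAL4 unsorted replicate 2 their medians went from -0.45 and 1.15 to -0.013 and -0.048. Of the 2 medians only that of the ribosomal protein genes changed sign. Scaling moved the median of all genes from -0.09 to -0.65 with library totals and to -0.24 after quantile normalization in the eya-GAL4 enrichment, and from -0.08 to -0.18 with median-of-ratios in the tj-GAL4 enrichment. It moved from 0.12 to 0.30 and -0.04 in the sorted comparison, from -0.03 to 0.56 and -0.16 in the interaction, and from 0.14 to -0.25 and 0.11 in the unsorted comparison, with library totals and median-of-ratios. Of 150 list tests, camera at the preset correlation called 76. All 76 calls were lost with an estimated correlation, and 50 of them with fry. Of 233 calls of named genes, DESeq2, a robust spread, no filter and the fit without mitochondrially encoded genes kept all. None changed sign in any setting. Limma on log2(RPM + 1) lost 98 of them, against 11 after quantile normalization of the same values. With that normalization limma made 1401 calls for the tj-GAL4 and 6235 for the eya-GAL4 enrichment. The loss by limma thus depended on the scaling of the RPM. The tj-GAL4 libraries of the same number deviated from their group means with a correlation of -0.351 across genes, which are not independent replicates. As their unsorted replicate 2 stood apart, this can neither show nor exclude pairing or a shared batch. Both replicate 1 libraries carry 6-base indexes. A block over these numbers lost 14 of the named calls and kept 217. Apart from fewer libraries or genes in the fit and the scaling of the RPM, the cause was not tested. Changes under 4-fold were mostly not recovered in simulated data, 31.7% at 4-fold in the tj-GAL4 enrichment.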

Other observations

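The percentages of a list, and those of the gut list, rest on tests chosen only after the result was seen. Relative to eya-GAL4 unsorted cells, the median level of early cyst genes was 459.4% and 366.6% in tj-GAL4 sorted replicates 1 and 2 and 414.3% and 347.9% in eya-GAL4 sorted replicates 1 and 2. Spermatocyte genes lay at 33.8% and 45.8% in the tj-GAL4 and at 24.6% and 24.2% in the eya-GAL4 sorted libraries. Muscle genes lay at 26.8% and 15% against 64.1% and 69.1%. Early germline genes lay at 129.8% and 150.3% against 76.5% and 61.7%.

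The gut list lay at a median log2 ratio of 0.03 in tj-GAL4 unsorted replicate 1, 3.34 in replicate 2, and 0.19 and -3.19 in eya-GAL4 unsorted replicates 3 and 4, each against the other unsorted libraries. The gut trypsin gene alphaTry was at 1036 CPM in tj-GAL4 unsorted replicate 2 and at 2.89 CPM in eya-GAL4 unsorted replicate 4. The gene counts made up 49.7% of the total behind the authors' RPM in tj-GAL4 unsorted replicate 2 and 28.0% in eya-GAL4 sorted replicate 1.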
